A study of Mus musculus with 18 samples.

How the data were processed

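Poly(A) RNA from 18 cultures of mouse CD4+ T cells was sequenced, 3 libraries in each of 6 groups. Per the labels, naive cells came from spleen and lymph nodes of wild-type mice and were polarized to pTh17 or betaTh17 cells, with 50 mM fructose in the treated cultures, and RNA was prepared with a Direct-zol kit. The extraction protocol gives 4 days of culture for all samples, while sample titles and design text give 2 or 4 days; the days in the titles were used. Sample titles write CTH17 where the cell type field says beta-Th17, and these were taken as the same cells.

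The deposited table holds counts of reads per gene, per the file headers and checked as whole numbers, for 54532 genes. It also holds, per the file headers, a gene length column (unit type: other), used only for length offsets. The authors trimmed reads with fastp; its version, the aligner, the counting tool, the genome build and the strand setting are not given in the sources used here. Because the strand setting is unknown, genes that overlap on opposite strands cannot be told apart. Reads of near-identical paralogs, such as Csf2rb and Csf2rb2, Hspa1b and Hspa1a, Ighg2c and other Ighg genes, or Ifitm3 and its relatives, may be assigned to either. Identifiers of 54495 genes matched GENCODE M21 (GRCm38), with the same start and end for 53585 (98.3%); positions in the text are those of the file.

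In each library 12857 to 13726 genes had at least 10 counts (median 13342). The 50 most abundant genes held 11.7% to 13.2% of counts. Replicates varied beyond counting error, with a chi-squared per degree of freedom of 13.4 to 136.8 within groups for genes of at least 20 counts.

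Analysis used R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr on the groups, leaving 14889 genes that held 99.9% of counts. TMM factors were 0.884 to 1.11. A quasi-likelihood model with a mean for each group was fitted to the 18 libraries together (12 residual degrees of freedom, common biological coefficient of variation 0.288). Tests were adjusted by Benjamini and Hochberg over all tested genes within a comparison, with calls at an adjusted p under 0.05, and no adjustment was made across the 8 comparisons. These were fructose against control at day 4 in pTh17 and in betaTh17 cells, their interaction, pTh17 against betaTh17 at day 2 and at day 4, day 4 against day 2 in each polarization, and the polarization by day interaction. Standard errors of log2 changes came from the F statistic, and CPM are TMM-scaled means with SD over libraries. Principal components used log2 CPM with a prior count of 2.

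Fixed gene lists, 45 in all, were written before the data were examined, as were the groups, comparisons, rule for naming genes and the first set of alternative settings. The 41 lists with at least 4 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Member genes were counted over all tested genes and, separately, with p-values adjusted over the list alone. Lists share some genes, so their tests are not independent.

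Genes were named by a rule: the 6 largest rises and 6 largest falls with an adjusted p under 0.05, no overlap between the compared libraries and a mean of at least 5 CPM in the higher group (3 and 3 for the day comparisons and the polarization by day interaction); a panel fixed in the same way, with Il17a, Il17f, Il23r, Csf2, Il22, Il10, Foxp3, Tbx21, Ifng and Egfr; and up to 4 members of lists that passed, for at most 6 lists in a comparison. Results of 5 genes that the rule names, and 1 test that used such a gene, are withheld and left out, without other genes in their place. Predicted genes, pseudogenes, mitochondrial genes and antigen receptor segments were left out of the largest changes. The chance that 3 and 3 libraries do not overlap in either direction is 10% for a gene without a difference. Pkd2, Cd79b, Ms4a1, Ebf1, Bank1, H2-Aa, H2-Ab1, Csf3r and Hba-a1 lie outside the rule and were chosen after their values were seen. Where a group had fewer than 4 counts, a count ratio with an exact 95% interval or a bound against a floor of 3 counts is given. Of the gene symbols, 103 belong to more than 1 identifier, and each identifier was kept apart.

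Alternative settings fixed before the data were examined were RLE size factors, no low-count filter, DESeq2 1.42.0, a fit of only the compared groups, replicate number as a block (replicate block), and leaving out each library in turn. Alternatives added after results were seen were a block of replicate number within day, offsets for GC content and gene length (5 spline degrees of freedom), the 2 together, leaving out replicate 3 of the betaTh17 day 2 controls, and the average of both fructose effects. Pairing was checked in the data as the correlation of residuals between libraries of the same replicate number, called paired where all 3 correlations exceeded 0.1, since the labels do not state it. This held for fructose in pTh17 cells (0.20, 0.15, 0.35) and for the polarizations at day 2 (0.35, 0.11, 0.31) and day 4 (0.23, 0.28, 0.40). Correlations of each library with those of other groups were also averaged by replicate number. For 16 of the 18 libraries this mean was highest for their own number.

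The method was tested on simulated data with known changes in 50 genes per size. In the pTh17 fructose comparison it recovered 2%, 28%, 94% and 98% of genes changed 1.5, 2, 4 and 8-fold, with 8 false among 119 calls, and in the interaction 0%, 2%, 62% and 84%. A gene without a call may thus still differ by 2-fold. The simulated libraries behind these figures varied independently around a common mean per gene, without the shared composition of some real libraries. Their false calls therefore do not give the error rate in the real data. Group labels were permuted to see how many calls arise without the real grouping. All 10 splits were used for comparisons of 2 groups. For the interactions and the averaged fructose effect 100 splits, the real grouping included, were drawn at random from those possible (seed 20).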

Results

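RNA sequencing was used to compare 2 kinds of mouse Th17 culture, with and without added fructose. Th17 cells are CD4+ helper T cells that make interleukin 17. Naive CD4+ T cells from spleen and lymph nodes of wild-type mice were polarized in culture either towards pTh17 cells, the pathogenic kind of the study's title, or towards the cells that the labels call betaTh17. The labels give no cytokine mix for either. Control cultures were collected at day 2 and day 4, and cultures with 50 mM fructose at day 4. This gave 6 groups of 3 libraries: betaTh17 day 2, pTh17 day 2, betaTh17 day 4, pTh17 day 4, and the betaTh17 and pTh17 day 4 cultures with fructose. The deposited table held counts for 54532 genes, and the library totals ran from 14858377 to 17570458 counts. All libraries gave male-type counts, with Ddx3y at 7.56 to 19.5 CPM (counts scaled to library size, here without TMM factors), Eif2s3y at 9.53 to 23.4 CPM and Xist at up to 0.119 CPM. The labels do not state whether replicates were separate mice or repeated cultures, so p-values measure only the spread between these samples, which may be technical.

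Time in culture and polarization separated the groups. The first principal component (37.3% of the variance) separated day 2 from day 4, and the second (15.8%) separated pTh17 from betaTh17. On the third (12.6%), libraries of 1 group lay far apart: the betaTh17 day 4 controls were at 39.9, -26.7 and -25.4, and the fructose-treated pTh17 libraries at 33.0, -43.0 and -0.96. Replicate 3 of the betaTh17 day 2 controls stood apart in composition, with mitochondrial transcripts at 0.719% of its counts and a median log2 deviation of 0.63 for GC-rich genes. Mitochondrial transcripts ranged from 0.216% to 0.733% over all libraries, and ribosomal protein genes from 0.489% to 1.24%. The highest value of both was that of pTh17 fructose replicate 2, where GC-rich genes deviated by -0.21. Markers of granulocytes and of red cells and platelets stayed near the floor, with highest values of 0.633 CPM (Csf3r) and 0.928 CPM (Hba-a1) in any library.

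**Figure D1:**
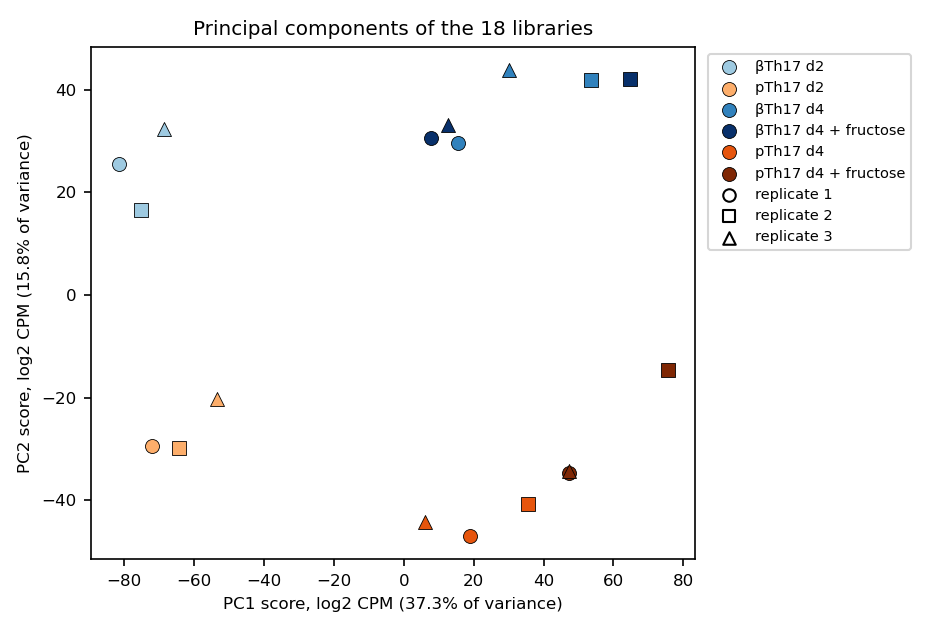
Scores of the 18 libraries on the first (37.3% of variance) and second (15.8%) principal components of log2 CPM, coloured by group, with a marker shape for each replicate number. Day 2 libraries lie on the left, day 4 libraries on the right, and pTh17 libraries below betaTh17 libraries.

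The main question, as the series title puts it, was what fructose does to pathogenic Th17 cells. In pTh17 cells at day 4, Dll4, Trp53inp1 and Btg2 were higher with fructose in the fit of all 18 libraries. Ciita, Spi1 and genes of the B cell marker list were lower. No gene was called when only the compared groups were fitted, without fructose replicate 1 or without control replicate 3. Dll4, a Notch ligand (chromosome 2, 119325784 to 119335962), rose 4.45-fold, from 6.28 ± 1.45 to 28.0 ± 11.8 CPM (SD, n = 3; log2 change 2.16 ± 0.31 SE, adjusted p = 0.00658). Trp53inp1, a stress gene induced by p53 (chromosome 4, 11156431 to 11174379), rose 3.72-fold to 140 ± 37.2 CPM, and Btg2, an antiproliferative gene, rose 3.96-fold to 58.8 ± 22.2 CPM. The other genes with the largest rises were Slc13a3, a dicarboxylate transporter (log2 change 1.97, 16.9 ± 1.92 against 4.31 ± 1.28 CPM), Gprasp2 (2.01) and the tetraspanin Tspan6 (2.90, from 0.906 ± 0.145 CPM). Adjusted p-values of these 6 genes ran from 0.00658 to 0.0461.

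The genes with the largest falls were Trabd2b (log2 change -4.05), Csf2rb (-3.34), Ciita (-3.09), Mef2c (-2.72), Pld4 (-2.67) and Spi1 (-2.65), with adjusted p-values from 0.0189 to 0.0499. Control replicate 3 carried part of this: Csf2rb was at 15 CPM there against 2.82 and 2.18 CPM in controls 1 and 2, and without it the log2 changes were -1.87 for Csf2rb, -1.80 for Mef2c, -2.11 for Ciita and -2.82 for Trabd2b. Ciita encodes the master regulator of MHC class II genes, Spi1 the transcription factor PU.1 of B and myeloid cells, and Csf2rb the receptor chain shared by GM-CSF, IL-3 and IL-5. Counting may have split reads between Csf2rb and its close paralog Csf2rb2, so its value is uncertain. Ciita stood at 3.98 ± 2.14 CPM with fructose against 33.9 ± 27.8 CPM without.

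Of the 10 tested genes on the B cell marker list, 3 fell, 0 rose and 7 did not pass over all genes tested; adjusted over the list alone, 5 fell. Pax5, the factor that fixes B cell identity (chromosome 4, 44524757 to 44710487), fell 4.98-fold, from 126 ± 70.2 to 25.4 ± 10 CPM (adjusted p = 0.0149), and Blnk, a B cell receptor adaptor, fell 4.4-fold. Cd79a, a B cell receptor chain, was at 12.6 ± 2.31 against 37.7 ± 11.1 CPM (adjusted p = 0.0728; 0.00313 with replicate as a block (paired), and 0.0492 without replicate 3 of the betaTh17 day 2 controls, in a range of 8.11e-05 to 0.415 over its alternatives). By contrast Cd79b, the partner of Cd79a, reached at most 3.79 CPM in any library, and the mature B cell marker Ms4a1 averaged 0.378 ± 0.164 CPM in untreated pTh17 day 4 cells. The list as a whole was lower (mean log2 change -1.23, camera adjusted p = 3.15e-06; adjusted p = 0.728 with an estimated correlation).

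**Figure D2:**
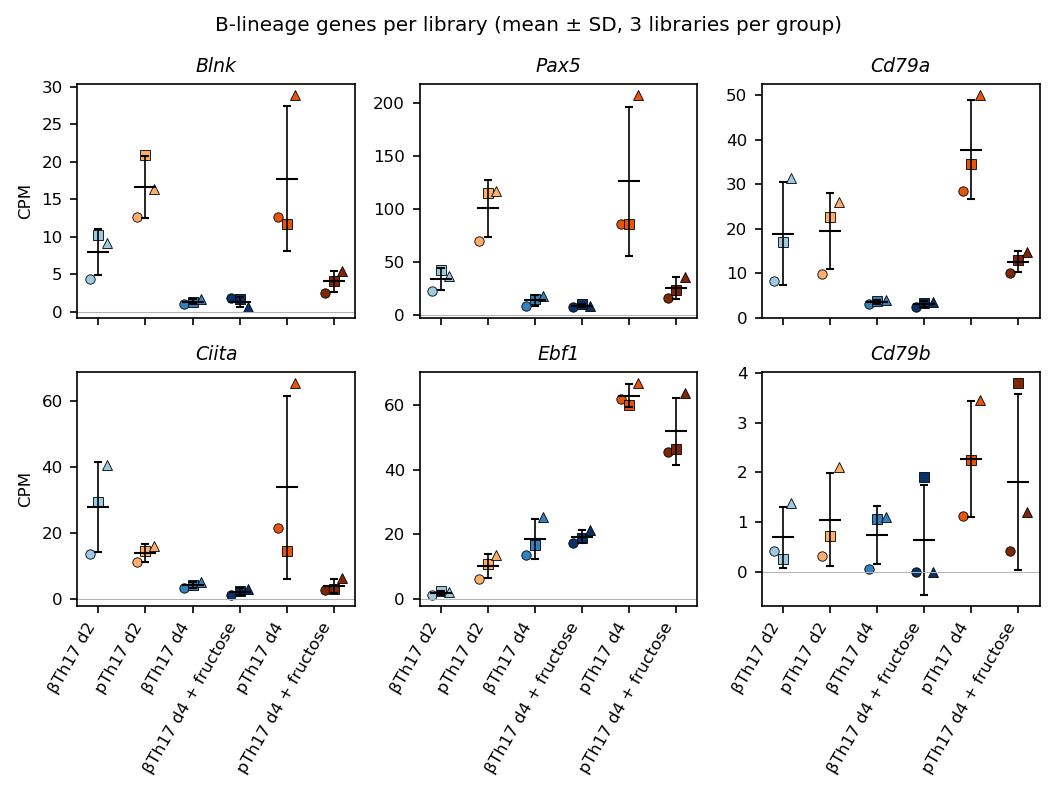
Expression in CPM (linear axis, own scale in each panel) of 6 B-lineage genes in each of the 18 libraries, by group, with horizontal bars for the mean and error bars for the SD of 3 libraries. Pax5 averages 126 CPM in untreated pTh17 day 4 libraries and 25.4 CPM with fructose, while Cd79b stays below 3.8 CPM throughout.

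Cell cycle genes were lower as a group with fructose in pTh17 cells (23 tested, mean log2 change -0.44, camera adjusted p = 0.000337; adjusted p = 0.862 with an estimated correlation). None of the 23 passed over all genes tested, and 3 were lower adjusted over the list alone. The mitotic kinases Cdk1 and Plk1 stood at log2 changes of -0.80 and -0.86, cyclin gene Ccna2 at -1.19 and the ribonucleotide reductase gene Rrm2 at -1.26. Amino acid transport genes of the mTORC1 list were also lower (12 tested, mean -0.28, adjusted p = 0.0281; adjusted p = 0.728 with an estimated correlation, and 0.0541 with the replicate block). None passed over all genes, and 5 were lower adjusted over the list alone. Among them Slc7a5, part of the large neutral amino acid transporter, was at 639 ± 204 against 1169 ± 122 CPM, with Slc7a1 (-0.78), Slc3a2 (-0.59) and Slc38a2 (-0.60) beside it. With the replicate block the adjusted p fell to 0.0234 for Cdk1, 0.0337 for Plk1, 0.0417 for Rrm2, 0.032 for Slc38a2, 0.0491 for Slc7a1 and 0.0415 for Slc7a5, where the alternatives of these 6 genes spanned 1.72e-05 to 0.520. Rrm2 also passed without fructose replicate 3 (log2 change -1.94, adjusted p = 0.0373), but its adjusted p was 0.516 without fructose replicate 2. Its log2 change ran from -1.94 to -0.95 when a library was left out. The p53 list was higher (13 tested, 1 called over all genes and 1 adjusted over the list alone, Trp53inp1; mean 0.51, adjusted p = 0.0123; adjusted p = 0.728 with an estimated correlation). Its members Fas, Mdm2 and Phlda3 stood at 1.03, 0.46 and 0.57 without passing (0.49 to 1.36, 0.21 to 0.60 and 0.37 to 0.70 when a library was left out; Fas was lowest without fructose replicate 2).

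Of the Th17 cytokine and regulator genes chosen in advance, none passed in pTh17 cells with fructose in the fit without pairing. Il17a (chromosome 1, 20730905 to 20734496) averaged 157 ± 104 CPM with fructose and 36.7 ± 13.6 CPM without (log2 change 2.10 ± 0.86, adjusted p = 0.235). Fructose replicate 1, at 37.9 CPM, lay inside the control range of 22.0 to 48.9 CPM, and replicates 2 and 3 were at 230 and 203 CPM. Against the control of the same number (22.0, 39.0 and 48.9 CPM) Il17a was higher in all 3 pairs, as were Il17f and Il23r. With a within-day replicate block, added after results were seen, the adjusted p was 0.00213 for Il17a (log2 change 1.79), 0.0117 for Il17f, 0.0304 for Il23r and 0.0213 for Tbx21, in a range of 6.87e-15 to 0.809 over the alternatives of these 4 genes. Il17f stood at 261 ± 123 against 123 ± 25.3 CPM (adjusted p = 0.385). Il23r, the receptor for the cytokine that sustains pathogenic Th17 cells, stood at 15.6 ± 1.46 against 9.32 ± 2.97 CPM (0.241). Log2 changes were -0.71 for Tbx21, the Th1 regulator, 0.28 for Il22 (-0.11 with the replicate block, -0.25 without fructose replicate 2) and -0.10 for Il10 (0.21 without fructose replicate 1, 0.54 without control replicate 3). Foxp3, the regulatory T cell factor, was at 12 ± 5.14 against 28.9 ± 11.8 CPM (adjusted p = 0.0852). It passed with the replicate block (0.00664) and without fructose replicate 3 (-1.62, 0.0481), in a range of 0.00158 to 0.467. The highest of these was without control replicate 3, and its log2 change ran from -1.62 to -0.81 when a library was left out. Egfr, which the study's title names, stood at 37.9 ± 6.81 against 29.4 ± 2.41 CPM (adjusted p = 0.377). Csf2, the GM-CSF gene, had 37 counts over the 3 fructose libraries against 15, and Ifng, too low to be tested, 31 against 8. Single libraries carried much of both. Csf2 was at 0.243, 0.391 and 1.575 CPM with fructose against 0.063, 0.182 and 0.633 CPM. Its log2 change ran from 0.10 to 2.57 when a library was left out. Ifng was at 0.304, 1.395 and 0.061 CPM with fructose against 0, 0.182 and 0.288 CPM.

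**Figure D3:**
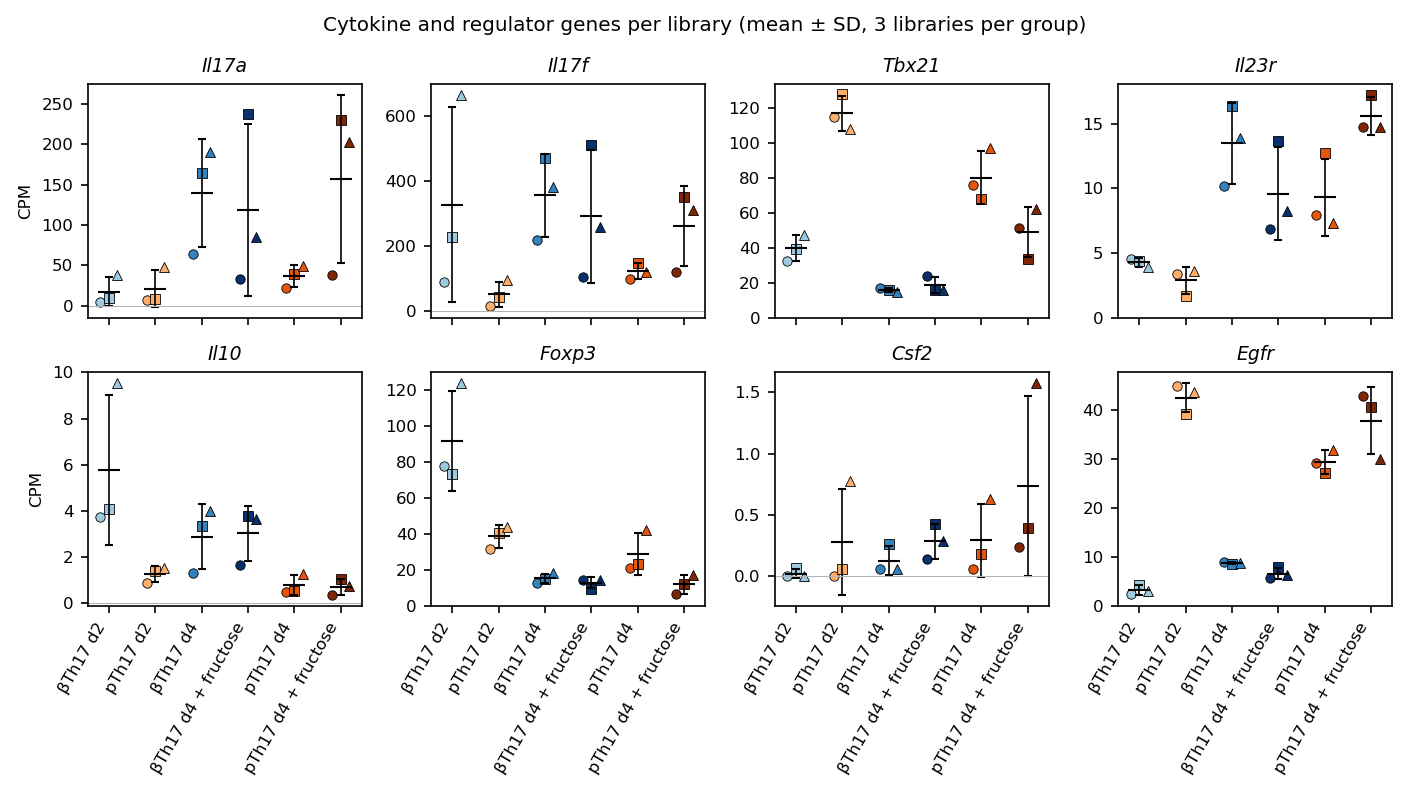
Expression in CPM (linear axis, own scale in each panel) of 8 cytokine and regulator genes in each library, by group, with bars for the mean and SD of 3 libraries. Egfr is at 29.4 CPM in pTh17 and 8.78 CPM in betaTh17 day 4 controls, and Il17a varies more than 5-fold between pTh17 libraries with fructose.

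As lists, the pathogenic Th17 genes had a mean log2 change of 0.43 (15 tested, 0 called, and 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.353, and 0.951 with an estimated correlation; mean 0.19 without fructose replicate 3 and 0.92 without control replicate 3). The non-pathogenic Th17 genes had a mean of -0.11 (adjusted p = 0.729; mean 0.09 without fructose replicate 1 and 0.31 without control replicate 3). Lists on the study's proposed route also did not pass: EGFR family and ligands (mean 0.22, adjusted p = 0.371), NADPH oxidase (-0.26, 0.746), NRF2 antioxidant genes (-0.13, 0.305) and fructose and polyol metabolism (0.52, 0.305). Neither did markers of dendritic cells (-0.66, 0.305) or myeloid cells (0.41, 0.923), though Spi1 belongs to the latter. In all, 80 genes were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 25 higher and 55 lower, of 14889 tested (2576 at an unadjusted p under 0.05). DESeq2 called 384 and the fit with the replicate block 598, which included all 80. The count rested on few libraries: it was 0 without fructose replicate 1, 0 without control replicate 3, 3 without fructose replicate 2, 26 without control replicate 1, and 0 when only these 6 libraries were fitted. All 14 named genes that passed were lost without fructose replicate 1 or without control replicate 3, where the adjusted p-values ran from 0.0649 for Dll4 to 0.387 for Mef2c. All but Dll4 were lost without fructose replicate 2 (up to 0.192 for Tspan6), against a range of 2.64e-15 to 0.387 over all alternatives. Smaller losses were those of Blnk, Btg2, Gprasp2, Slc13a3, Tspan6, Trp53inp1 and Mef2c without control replicate 1 (0.0813 to 0.160), Tspan6 without control replicate 2 (0.0848), Mef2c and Pld4 without fructose replicate 3 (0.075 and 0.0611) and Mef2c without replicate 3 of the betaTh17 day 2 controls (0.0631).

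In betaTh17 cells at day 4, 1 gene was called with fructose over all 14889 tested. Pkd2, the calcium channel polycystin 2, fell to 0.905 ± 0.186 from 3.88 ± 0.647 CPM (log2 change -2.10 ± 0.30 SE, edgeR adjusted p = 0.0246); it was named after its value was seen. The Th17 core list was lower as a group (17 tested, 0 called, 1 lower adjusted over the list alone; mean log2 change -0.42, camera adjusted p = 0.00382). With an estimated correlation, this and the other 6 lists that passed in betaTh17 cells had adjusted p-values of 0.792 to 0.799. The members of smallest p were the IL-1 receptor gene Il1r1, at 13.0 ± 6.10 against 26.8 ± 5.65 CPM, and Tmem176a, Il17re and Il21, at log2 changes of -1.19, -0.69 and -0.55. Changes as large were those of Il22 (-1.29) and Tmem176b (-1.03), and of Ccr6 (0.72) in the other direction, the last 2 named after their values were seen. In pTh17 cells Tmem176a (-1.77), Tmem176b (-1.39) and Il1r1 (-0.68) were lower too, without passing, while Il17re (0.24) and Il21 (0.34) were not lower. Over the alternatives in betaTh17 cells the smallest adjusted p was 0.0218 for Il1r1 and 0.0363 for Tmem176a, though neither passed in the main fit. Cholesterol synthesis genes were lower by a small amount (22 tested, 0 called, 0 adjusted over the list alone, mean -0.24, adjusted p = 0.00382), with Mvk at -0.49 and Mvd at -0.33. In pTh17 cells Mvk was lower as well, at 57.6, 49.6 and 60.1 against 89.3, 80.4 and 82.0 CPM in controls 1 to 3. Mvd was at 311, 307 and 304 against 331, 301 and 306 CPM there. The p53 list was higher here too (13 tested, 0 called, 0 adjusted over the list alone; mean 0.29, adjusted p = 0.00862; Mdm2 0.36, Phlda3 0.47, Cdkn1a 0.30, Zmat3 0.25). Without fructose replicate 2 Phlda3 was at 0.14, Cdkn1a at 0.08 and Mdm2 at 0.24.

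Genes of the osmotic response were higher as a group in fructose-treated betaTh17 cells (10 tested, 0 called, 1 higher adjusted over the list alone; mean 0.42, adjusted p = 0.0369). The heat shock gene Hspa1b, whose counts may include reads of its near-identical copy Hspa1a, was at 10.2 ± 2.05 against 4.72 ± 0.449 CPM. Hspa4l stood at 0.50 and the taurine transporter gene Slc6a6 at 0.27, and Slc6a12, a betaine transporter gene, had 11 against 2 counts, a ratio of 5.74 (95% counting interval 1.25 to 53.3). In pTh17 cells the same list had a mean of 0.39 and an adjusted p of 0.467. There Hspa4l was at 47.9, 45.4 and 46.9 CPM with fructose against 26.8, 29.9 and 28.7 CPM in controls 1 to 3. Slc6a6 was lower with fructose in pair 2 and higher in the others. MAPK feedback genes were higher in betaTh17 cells (17 tested, 0 called, 0 adjusted over the list alone; mean 0.23, adjusted p = 0.0176). Dusp1 stood at 0.44, Errfi1, an inhibitor of EGFR, at 0.54, Spry2 at 0.55 and Fosl1 at 0.46. In pTh17 cells Errfi1 was at 15, 16.4 and 13.8 CPM with fructose against 5.8, 6.6 and 5.9 CPM in controls 1 to 3. Spry2 went the other way there, at 6.5, 3.68 and 8.96 against 16.2, 11.6 and 18.2 CPM. Dusp1 and Fosl1 were higher with fructose in each pTh17 pair. Leaving out a library in betaTh17 cells moved Dusp1 to 0.28 to 0.68 and Errfi1 to 0.19 to 0.70. Spry2 moved to 0.28 to 0.87 and Fosl1 to 0.24 to 0.67. Mitochondrially encoded transcripts were lower (12 tested, 0 called, 0 adjusted over the list alone; mean -0.42, adjusted p = 0.0171), among them mt-Nd2 (-0.77), mt-Cytb (-0.67), mt-Nd5 (-0.52) and mt-Nd4 (-0.48). Control replicate 3 stood apart, with mt-Nd2 at 788 CPM against 266 and 475 CPM in controls 1 and 2, and without it these were at -0.31, -0.39, -0.32 and -0.39. Type I interferon genes were lower too (11 tested, 0 called, 0 adjusted over the list alone; mean -0.42, adjusted p = 0.0482; 0.06 with GC and length offsets). Adjusted p-values of these 7 lists with an estimated correlation lay between 0.792 and 0.799.

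The chosen cytokine genes gave no calls in betaTh17 cells in the main fit. Il17a was at 119 ± 107 CPM with fructose and 140 ± 66.9 CPM without, and its log2 change of -0.23 turned positive without fructose replicate 1 (0.21) or control replicate 3 (0.06). Il17f stood at -0.29 (0.11 without fructose replicate 1). Il22 was at 5.39 ± 4.74 against 13.3 ± 8.50 CPM, Il23r at -0.49, Foxp3 at -0.25, Tbx21 at 0.23 (-0.83 to -0.30, -0.37 to -0.07 and 0.01 to 0.34 when a library was left out) and Egfr at 6.60 ± 1.19 against 8.78 ± 0.255 CPM. The log2 change of Il22 (-1.29) ran from -2.19 to -0.81 when a library was left out. Its smallest adjusted p over the alternatives was 0.0168. Il10, at 0.07, turned negative without control replicate 1 (-0.27), fructose replicate 2 (-0.12) or fructose replicate 3 (-0.08). Csf2 had 15 against 7 counts, and Ifng 2 against 15, a ratio of 7.19 in favour of the control (95% counting interval 1.67 to 64.8). Control replicate 3 carried most of the Ifng counts, at 0.638 CPM against 0 and 0.212 CPM in controls 1 and 2. B cell markers had a mean of -0.26 (adjusted p = 0.216). At an unadjusted p under 0.05, 622 genes passed; DESeq2 called 33. The call of Pkd2 was lost without control replicate 1, 2 or 3 or fructose replicate 1 or 3 (0 calls each), and without fructose replicate 2 the 1 call was another gene.

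Whether fructose acts differently on the 2 kinds of Th17 cell was tested as an interaction, the pTh17 effect minus the betaTh17 effect. No gene passed by edgeR (smallest adjusted p = 0.641; 949 genes at an unadjusted p under 0.05), and DESeq2 called 3. Day 4 libraries of the same replicate number went together in 5 of the 6 pairs of groups. The pair that failed was betaTh17 control against fructose (r = 0.61, 0.65 and 0.09), which is part of this interaction. The pairing behind a block is thus not met for the whole contrast. With the replicate block fixed in advance 0 genes passed, as with only the compared groups. With the within-day replicate block, added after results were seen, 103 genes passed. Named genes among them were Pax5 (0.0313), Cd79a (0.0419), Ccna2 (0.0413), Rrm2 (0.0419), Il17a (0.0385) and Il17f (0.0481), in a range of 1.61e-08 to 0.992 over the alternatives of these 6 genes. B cell genes differed as a list (10 tested, 0 called, 3 lower adjusted over the list alone; mean -0.97, camera adjusted p = 0.00426), with Blnk at -2.17, Pax5 at -1.63 and Cd79a at -1.36. With an estimated correlation, this and the other 4 lists that passed had adjusted p-values of 0.687 to 0.708. Cell cycle genes also went lower in pTh17 than in betaTh17 cells (23 tested, mean -0.39, adjusted p = 0.00875; Ccna2 -1.5, Rrm2 -1.38, Plk1 -0.93, Cdk1 -0.74). In the other direction lay genes of the TCA cycle (20 tested, mean 0.71, adjusted p = 0.0201; Mdh1 2.33, Sdhd 2.2, Sdhb 1.18, Idh2 0.72). Mdh1 was at 62.0 CPM in pTh17 fructose replicate 2, the library with the highest mitochondrial and ribosomal protein shares, against 5.59 and 15.9 CPM in replicates 1 and 3, and its value ran from 0.95 to 4.61 when a library was left out (Sdhd 1.03 to 3.48). In betaTh17 cells Mdh1 was at 30.9, 55.9 and 35.4 CPM in control 2, fructose 2 and control 3, and at 4.31 to 5.73 CPM in the other libraries of day 4. The Th17 core list (17 tested, mean 0.44, adjusted p = 0.0332; Il23r 1.23, Il21 0.90, Batf 0.85) and the hypoxia list (17 tested, mean 0.55, adjusted p = 0.0332, and 0.0562 with GC and length offsets; Car12 1.5, Ero1l 0.99, Ndrg1 0.82, Kdm3a 0.59) were also higher. Ero1l followed the same betaTh17 libraries as Mdh1, at 456, 504 and 342 CPM against 161 to 228 CPM in the others, and ran from 0.70 to 1.66 when a library was left out (Ndrg1 0.58 to 1.28, Car12 1.14 to 2.16, Kdm3a 0.38 to 0.85). In the fit without pairing none of the members of these 4 lists passed, over all genes tested or adjusted over the list alone. Il17a had an interaction of 2.33 ± 1.18 on the log2 scale (adjusted p = 0.641), Il17f 1.38, Il22 1.57, Egfr 0.77, Foxp3 -1.02 and Tbx21 -0.94. Il17a was also high in betaTh17 control 2, fructose 2 and control 3 (164, 238 and 191 CPM against 32.8 to 85.2 CPM in the others), as were Il21 (70.2 to 108 against 41.7 to 56.0 CPM) and Il23r (13.7 to 16.4 against 6.87 to 10.2 CPM). When a library was left out the values ran from 1.89 to 3.34 for Il17a, 0.98 to 2.06 for Il17f, 1.04 to 2.47 for Il22, -1.36 to -0.57 for Foxp3 and -1.98 to -1.02 for Pax5. Csf2 (0.18) and Il10 (-0.18) changed sign when a library was left out. Csf2 was at -0.12 without betaTh17 fructose replicate 1, -0.88 without betaTh17 control replicate 2, -0.23 and -0.07 without pTh17 control replicates 1 and 2, and -1.01 without pTh17 fructose replicate 3. Il10 was at 0.17 and 0.01 without betaTh17 control replicate 1 and fructose replicate 2, and at 0.13 and 0.45 without pTh17 fructose replicate 1 and control replicate 3.

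No gene was called with fructose in both kinds of cell, against an expected 0.00369 for independent lists; DESeq2 called 14 in both, all in the same direction. Of the 80 genes called in pTh17 cells, 68 (85%) had the same sign in betaTh17 cells, where the share over all genes tested was 49.6%. Among the larger sets called in other settings the share was 85.7% (DESeq2, 384 genes), 79.1% (replicate block, 598) and 56.7% (within-day replicate block, 2085). The genes called higher had a median log2 change of 1.65 in pTh17 and 0.62 in betaTh17 cells, and those called lower -1.86 and -0.58. Across the 14889 genes, which are not independent replicates, the fructose effect in pTh17 cells at day 4 had a Pearson r of 0.0042 with the difference between the polarizations at day 2 (Spearman rho 0.0308). Of the splits, 9 of the 10 possible with the 6 pTh17 libraries gave an r as large.

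The polarizations themselves differed widely at day 2. Egfr, the epidermal growth factor receptor gene (chromosome 11, 16752203 to 16918158), was 13.1-fold higher in pTh17 cells, at 42.6 ± 2.99 against 3.25 ± 0.971 CPM (log2 difference 3.71 ± 0.25, adjusted p = 1.84e-08). Genes of the non-pathogenic Th17 list were lower (8 tested, 6 lower and 0 higher over all genes and adjusted over the list alone; mean -2.21, camera adjusted p = 2.31e-16; adjusted p = 0.000234 with an estimated correlation). Its member Ahr, the aryl hydrocarbon receptor gene (chromosome 12, 35497974 to 35535038), stood at 29.8 ± 1.64 against 447 ± 100 CPM, and Maf, a driver of Il10, at 196 ± 3.74 against 1909 ± 887 CPM. Ikzf3 (-1.94) and Il6st (-1.85), the shared IL-6 receptor chain, were lower too. Th17 core genes were also lower in pTh17 cells (17 tested, 6 lower, 7 adjusted over the list alone; mean -0.92, adjusted p = 0.0026, and 0.4 with an estimated correlation). Il1r1 was at -1.3, and Ccl20, the chemokine of CCR6, had 0 counts against 31, at least 10.9-fold lower against a floor of 3 counts over the group. Rora (-0.92) was lost without pTh17 replicate 3 (-0.79, adjusted p = 0.0527, in a range of 8.81e-05 to 0.0527).

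Th1 genes were higher in pTh17 cells at day 2 (12 tested, 4 higher, adjusted over the list alone 4 higher and 1 lower; mean 0.93, adjusted p = 0.00293, and 0.154 with an estimated correlation). Tbx21 stood at 117 ± 10 against 39.9 ± 7.35 CPM, Nkg7, a cytotoxic granule gene, at 10.5 ± 0.456 against 2.22 ± 0.441 CPM, Stat4 at 2.58 and Eomes at 2.29. The pathogenic Th17 list, which shares Tbx21 and Stat4 with the Th1 list, was higher (15 tested, 4 higher over all genes and adjusted over the list alone; mean 1.26, adjusted p = 0.00295, and 0.4 with an estimated correlation). It was led by the neutrophil chemokine gene Cxcl3 at 11.2 ± 1.62 against 0.561 ± 0.364 CPM, with Lrmp at 1.15. Glycolysis genes (22 entries, as Aldoa has a pair of gene identifiers; 2 higher, 4 adjusted over the list alone; mean 0.60, adjusted p = 0.000951, and 0.186 with an estimated correlation) included the hexokinase gene Hk2, at 440 ± 42.6 against 223 ± 34.8 CPM, and the glucose transporter gene Slc2a1 at 0.59. Hypoxia genes (17 tested, 4 higher and 1 lower, 9 and 1 adjusted over the list alone; mean 0.69, adjusted p = 0.00293, and 0.392 with an estimated correlation) included Ndrg1 (1.55), Ak4 (1.85), Bnip3 (1.86) and Bnip3l (0.99). Leaving out a library ended 4 of these calls. Stat4 was lost without betaTh17 replicate 1 (0.0574) or 3 (0.116), Bnip3l without betaTh17 replicate 3 (0.105) or pTh17 replicate 2 (0.0712). Eomes was lost without betaTh17 replicate 1 (0.1) or 3 (0.148) or pTh17 replicate 1 (0.0542) or 2 (0.157), and Slc2a1 without any of betaTh17 replicates 1 and 3 (0.0851, 0.054) and pTh17 replicates 1, 2 and 3 (0.0853, 0.118, 0.053). The alternatives of these 4 genes spanned adjusted p-values of 8.64e-06 to 0.157. Pdk1 (1.02, adjusted p = 0.0559) and Slc16a1 (0.89, 0.0567) passed with the replicate block (0.00248 and 0.0201), Pdk1 also without betaTh17 replicate 1 (0.0321) or pTh17 replicate 3 (0.0348), in a range of 0.000162 to 0.243.

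Another 10 lists passed at day 2, with adjusted p-values of 0.154 to 0.619 with an estimated correlation. Higher in pTh17 cells were T cell receptor activation (mean 0.80, adjusted p = 0.00295; 5 of 16 higher), heat shock (0.69, 0.00569), MAPK feedback (0.54, 0.00832), CD8 T cell markers (1.13, 0.016, which share Nkg7 with the Th1 list) and TCA cycle (0.47, 0.018). So were B cell markers (0.66, 0.0318; 3 of 10 higher) and EGFR family and ligands (0.45, 0.0497, and 0.0598 with the replicate block), where Egfr was the 1 gene called. Lower were mitochondrially encoded transcripts (-1.01, 0.0075), TGF-beta response (-0.58, 0.0111; 8 of 17 lower) and STAT3 targets (-0.60, 0.0111; 5 of 12 lower). For mt-Nd5 and mt-Cytb, betaTh17 replicate 3 stood apart: mt-Nd5 was at 979, 789 and 3269 CPM in betaTh17 replicates 1 to 3 against 720, 743 and 680 CPM in pTh17, and mt-Cytb at 242, 252 and 867 against 241, 206 and 228 CPM. With the replicate block 4 more lists passed: regulatory T cells (mean -0.46, 0.0917 to 0.0396), IL-1 and NF-kB (0.35, 0.0616 to 0.0238), cholesterol synthesis (0.32, 0.0823 to 0.0447) and chemokine receptors (-0.52, 0.0671 to 0.0134).

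The largest single differences at day 2 lay in genes that were almost off in 1 polarization. Higher in pTh17 cells were Dgkk, a diacylglycerol kinase (353 counts against 0, at least 112-fold), Zbtb7c (log2 difference 6.56), the transcription factor Twist1 (5.97), Stra6 (5.36), Il2 (5.36, 17.9 ± 4.08 against 0.432 ± 0.201 CPM) and Sema6a (5.30). Higher in betaTh17 cells were Lhx6 (603 counts against 2, ratio 317, 95% counting interval 87.3 to 2622), the water and glycerol channel gene Aqp3 (461 ± 127 against 2.40 ± 0.565 CPM), Mical2 (-7.09), Olfm2 (-6.98) and Tmeff1 (-6.82). All intervals and floors cover counting error only. Among the chosen cytokine genes, Il17a did not differ in the test (21.2 ± 23.3 against 17.4 ± 18.1 CPM, adjusted p = 0.879; log2 difference 0.28, but -0.14 with GC and length offsets, -0.18 without betaTh17 replicate 1 and -1.17 without pTh17 replicate 3). Il17f was lower in pTh17 cells, at 51.3 ± 39.5 against 327 ± 301 CPM (-2.67, adjusted p = 0.0176; 0.199 without betaTh17 replicate 3, 0.0775 and 0.0839 without pTh17 replicates 1 and 2). Il10 (-2.19, 0.00926; 0.0895 without betaTh17 replicate 3 and 0.054 without pTh17 replicate 1) and Foxp3 (-1.25, 0.0189; 0.112 without betaTh17 replicate 3, 0.087 and 0.0623 without pTh17 replicates 1 and 2) were lower as well. Il22 stood at 44.6 ± 55.0 against 11.1 ± 12.4 CPM (adjusted p = 0.226) and passed with the replicate block (0.0219). With no low-count filter its adjusted p was 3.63e-10, which is doubtful given this spread. The pTh17 mean of Il22 rested on replicate 3, at 108 CPM against 7.71 and 18.2 CPM in replicates 1 and 2. Il23r was at -0.57. Csf2 had 14 counts against 1, a ratio of 13.3 (2.03 to 563). Most of these came from pTh17 replicate 3, at 0.781 CPM against 0 and 0.061 CPM in replicates 1 and 2. Ifng had 8 counts against 5. The alternatives of Il17f, Il10, Foxp3 and Il22 spanned 8.19e-26 to 0.935. In all, 587 genes were higher and 851 lower in pTh17 cells (1438 called), with 880 calls without pTh17 replicate 2 and 932 without pTh17 replicate 3.

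At day 4 without fructose, Egfr remained higher in pTh17 cells, at 29.4 ± 2.41 against 8.78 ± 0.255 CPM (log2 difference 1.74, adjusted p = 6.6e-05). B cell markers were the list that differed most by p-value (10 tested, 6 higher, 7 adjusted over the list alone; mean 2.40, camera adjusted p = 1.45e-11; adjusted p = 0.169 with an estimated correlation). Pax5 was at 126 ± 70.2 against 13.7 ± 4.90 CPM (log2 difference 3.20) and Cd79a at 37.7 ± 11.1 against 3.62 ± 0.425 CPM (3.38), with Blnk (3.76) beside them. Dendritic cell markers were higher too (5 tested, 3 higher over all genes and adjusted over the list alone; mean 1.38, adjusted p = 0.00525, and 0.32 with an estimated correlation). Flt3 was at 20.1 ± 3.52 against 4.11 ± 2.26 CPM, and Zbtb46 at 2.21. Itgax, at 2.31, was lost without betaTh17 replicate 2 (0.0702) or 3 (0.0561) or pTh17 replicate 3 (0.0983), in a range of 0.00229 to 0.0983. Xcr1 did not differ in the test (0.13, adjusted p = 0.895; -0.01 without betaTh17 replicate 2 and -0.49 without pTh17 replicate 3).

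The non-pathogenic Th17 genes were again lower in pTh17 cells (8 tested, 5 lower, adjusted over the list alone 5 lower and 1 higher; mean -0.87, adjusted p = 1.13e-06; adjusted p = 0.0113 with an estimated correlation). Maf stood at 143 ± 16.1 against 821 ± 170 CPM, Ahr at -2.09, Il6st at -1.78 and Ikzf3 at -1.44. Th1 genes were higher (12 tested, 5 higher over all genes and adjusted over the list alone; mean 0.81, adjusted p = 0.000415, and 0.0934 with an estimated correlation). Among them were Tbx21 at 80.5 ± 15 against 15.9 ± 1.02 CPM, the chemokine receptor gene Cxcr3 at 59.3 ± 16.6 against 10.8 ± 1.62 CPM, Ccl5 at 1.42 and Eomes at 2.41. Th17 core genes were lower (17 tested, 4 lower and 1 higher, 6 and 1 adjusted over the list alone; mean -0.83, adjusted p = 0.00158, and 0.857 with an estimated correlation). Among them were Ccl20 at -5.18, Il21 at -1.3 and Il17re at -1.41. IL-1 and NF-kB genes were higher (15 tested, 3 higher, 5 adjusted over the list alone; mean 0.55, adjusted p = 0.0175, and 0.317 with an estimated correlation), with Cd83 at 2.2, Nfkbiz at 1.14, Icam1 at 0.80 and Nfkb2 at 0.73. Nfkb2 missed the threshold (0.0655) and passed with the replicate block (0.0236), without betaTh17 replicate 1 (0.0495) and without replicate 3 of the betaTh17 day 2 controls (0.0135). Cell cycle genes were lower (23 tested, 1 lower, 3 adjusted over the list alone; mean -0.39, adjusted p = 0.0231, and 0.857 with an estimated correlation), but not with GC and length offsets (0.0512). Ccl5 was lost without betaTh17 replicate 3 (0.0713) or pTh17 replicate 1 (0.0582) or 3 (0.0595). Eomes was lost without betaTh17 replicate 2 (0.138) or 3 (0.137) or pTh17 replicate 1 (0.0976) or 3 (0.0834), and Il17re without betaTh17 replicate 2 (0.0877) or pTh17 replicate 1 (0.102) or 3 (0.0918). Over their alternatives Ccl5, Eomes, Il17re and Nfkb2 spanned 3.23e-05 to 0.234.

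Single genes with the largest differences at day 4 were Zbtb7c (6.37, 46.1 ± 9.83 against 0.548 ± 0.256 CPM), Ighg2c (5.91), the scavenger receptor gene Scarf2 (5.76), the fatty acid receptor gene Ffar1 (5.70), the prostaglandin receptor gene Ptger3 (5.65) and Olfml2a (5.19), all higher in pTh17 cells. Ighg2c is an immunoglobulin constant gene, whose reads may be shared with its close relatives. Lower in pTh17 cells were the gap junction gene Gja5 (-5.62), Ccl20, Xkrx (-4.59), Cd101 (-3.94), Nov (-3.82) and Nt5e, which encodes the ectoenzyme CD73 (-3.77, 1.43 ± 0.0277 against 19.5 ± 3.43 CPM). Il17a stood at 36.7 ± 13.6 against 140 ± 66.9 CPM and Il17f at 123 ± 25.3 against 357 ± 128 CPM, both below betaTh17 levels but not passing (adjusted p = 0.175 and 0.164), with 0.0213 and 0.0241 with the replicate block. Il22 (1.67, 0.303) and Foxp3 (0.91, 0.0976) likewise passed with the replicate block (0.0182 and 0.0176) and with no low-count filter (1.55e-06 and 0.0262), these 4 genes spanning 5.66e-13 to 0.520 over their alternatives. The value of Il22 with no filter is doubtful, as at day 2. Foxp3 was at 42.3 CPM in pTh17 replicate 3 against 21.0 and 23.1 CPM in replicates 1 and 2, and its adjusted p reached 0.392. Il10 was lower (-1.89, 0.038; 0.117 and 0.163 without betaTh17 replicates 2 and 3, 0.171 and 0.132 without pTh17 replicates 1 and 2, in a range of 0.00138 to 0.171). Il23r was at -0.54, Csf2 had 15 against 7 counts (1.13, but -0.13 without pTh17 replicate 3), and Ifng 8 against 15. In all, 639 genes were higher and 422 lower in pTh17 cells (1061 called). DESeq2 called 1629 and the replicate block 2195, and the count was 630 and 564 without betaTh17 replicates 2 and 3, and 573 and 646 without pTh17 replicates 1 and 3.

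Between day 2 and day 4, pTh17 cells without fructose had higher levels of hypoxia, glycolysis and cytokine signalling lists. With an estimated correlation the 12 lists that passed had adjusted p-values of 0.231 to 0.725. Hypoxia genes (17 tested, 9 higher and 0 lower over all genes and adjusted over the list alone; mean 0.98, camera adjusted p = 6.62e-05) included P4ha2 (3.09), the oxygen sensor gene Egln3 (1326 ± 447 against 221 ± 27.2 CPM), Bnip3 (2.25) and Vegfa (1.76). Glycolysis genes (22 entries, 10 higher and 1 lower, 12 and 1 adjusted over the list alone; mean 0.72, 0.000132) included Aldoc (127 ± 44.8 against 11.8 ± 3.90 CPM), the lactate exporter gene Slc16a3 (1.61), Pfkm (1.38) and Aldoa (0.87). STAT5 and IL-2 response genes rose (11 tested, 9 higher and 1 lower over all genes and adjusted over the list alone; mean 0.75, 0.00058), with Socs2 (2.53), Cish (1.31), Bcl2 (1.22) and Il2rb (1.20). Il2 itself, another member, fell from 17.9 ± 4.08 to 0.913 ± 0.543 CPM. Th1 genes (mean 0.83, 0.0124; 4 of 12 higher, 6 adjusted over the list alone) rose with Il12rb2 (3.07), Runx3 (1.32), Il18r1 (1.24) and Hlx (1.13). Chemokine receptor genes (0.87, 0.0124; 4 of 12 higher over all genes and adjusted over the list alone) rose with Cxcr4 (3.39), Ccr6 (2.47), S1pr1 (2.22) and Ccr4 (1.61). STAT3 targets (0.89, 0.019; 6 of 12 higher and 1 lower both ways) rose with Il24 (4.90), Fos (3.21), Socs3 (1.60) and Pim1 (0.98). Th17 core (0.92, 0.0261), Th2 (1.19, 0.0414) and B cell genes (0.89, 0.044) were also higher, and T cell receptor activation (-0.50, 0.0313), heat shock (-0.61, 0.0437) and nuclear OXPHOS genes (-0.34, 0.044, and 0.0741 with GC and length offsets) lower. The largest single changes were rises of Foxf1 (7.24), the fibronectin gene Fn1 (7.10) and Rnf217 (6.17), and falls of Il2 (-4.28), Xkrx (-3.99) and Rgs16 (-3.81). In all, 1709 genes were higher and 977 lower at day 4 (2686 called), and 1657 were called without pTh17 day 4 replicate 2. Fitting only these 6 libraries gave 4310 calls. The labels do not say whether day 2 and day 4 libraries were prepared together.

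In betaTh17 cells metabolic lists rose over the same interval. Glycolysis genes (22 entries, 18 higher, 20 adjusted over the list alone; mean 1.78, camera adjusted p = 9.99e-15; adjusted p = 0.00404 with an estimated correlation) included Aldoc (193 ± 70.4 against 7.17 ± 2.23 CPM), the glucose transporter genes Slc2a3 (712 ± 426 against 27.4 ± 4.53 CPM) and Slc2a1 (1.49), and Slc16a3 (2.33). Hypoxia genes (17 tested, 14 higher, 15 adjusted over the list alone; mean 2.07, 4.66e-14; adjusted p = 0.0286 with an estimated correlation) included Bnip3 (4.85), P4ha2 (4.68), Ndrg1 (3.13) and Ak4 (2.83). Fatty acid synthesis genes rose (12 tested, 6 higher and 1 lower over all genes and adjusted over the list alone; mean 0.72, 0.0293; adjusted p = 0.128 with an estimated correlation), with Acss2 (2.63), Scd1 (2.11), Elovl6 (1.90) and Scd2 (1.33). The non-pathogenic list fell (8 tested, 5 lower over all genes and adjusted over the list alone; mean -1.33, 0.000232; adjusted p = 0.0286 with an estimated correlation), with Il6st (-1.71), Ahr (-1.56), Ikzf3 (-1.27) and Maf (-1.22). Dgkk, Nov and Scn9a went from 0 counts to 1615, 405 and 335, at least 478-fold, 120-fold and 99.1-fold higher, and Olfm2 (-7.24), Nat8l (-5.11) and Emid1 (-4.82) had the largest falls. In all, 2176 genes were higher and 1868 lower at day 4 (4044 called), with 2462 called without betaTh17 day 4 replicate 2.

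The change from day 2 to day 4 differed between the polarizations for 721 genes by the interaction test, 428 with a positive and 293 with a negative change in the value of pTh17 against betaTh17 from day 2 to day 4. With an estimated correlation the 9 lists that passed had adjusted p-values of 0.244 to 0.717. Glycolysis (mean -1.06, camera adjusted p = 9.88e-05; 1 of 22 lower, 10 adjusted over the list alone) and hypoxia genes (-1.10, 0.000252; 6 of 17 lower, adjusted over the list alone 8 lower and 1 higher) rose less in pTh17 than in betaTh17 cells. Bnip3 stood at -2.59, Ak4 at -2.30, Ndrg1 at -1.75, Pfkp at -1.74 and Kdm3a at -1.3. Among B cell genes (1.73, 0.000662; 3 of 10 higher, 6 adjusted over the list alone), Cd79a (3.33) and Blnk (2.69) passed. T cell receptor activation genes (-1.13, 0.000662; 6 of 16 lower and 1 higher, 6 and 2 adjusted over the list alone) included Il2 (-4.70), Egr3 (-2.17), Pdcd1 (-1.76) and Nr4a3 (-1.75). TCA cycle (-0.99, 0.00194; 0 of 20 called), cholesterol synthesis (-0.67, 0.00667; 2 of 22 lower) and nuclear OXPHOS (-0.61, 0.0402, and 0.0786 with GC and length offsets; 1 of 32 lower) were also lower. Non-pathogenic Th17 (1.34, 0.00667; 1 of 8 higher, Ahr at 1.82) and dendritic cell markers (1.48, 0.023; 1 of 5 higher, 3 adjusted over the list alone) were higher. Among TCA cycle genes, betaTh17 day 4 controls 2 and 3 stood apart. Mdh1 was at 5.73, 30.9 and 35.4 CPM in controls 1 to 3 there, against 6.10 to 6.21 CPM in pTh17 day 4 controls. Sdhd was at 4.88, 28.8 and 31.5 CPM, against 5.21 to 8.17 CPM. The difference in these genes thus rested on controls 2 and 3. With the replicate block the count of called genes was 1812 and DESeq2 gave 1307. Among genes that missed the threshold, Cd74 (1.89), Gpi1 (-1.17), Slc2a1 (-0.74), Slc2a3 (-2.13), Il1rn (2.82), Il9 (3.23), Aco1 (-1.27) and Suclg1 (-1.58) passed with the block at adjusted p-values of 0.00452 to 0.0465, in a range of 1.16e-09 to 0.473 over their alternatives. So did 2 lists, pathogenic Th17 (mean -1.19, 0.0662 to 0.0185) and mitochondrially encoded transcripts (0.94, 0.0507 to 0.0407). The count also fell without a library, to 452 without betaTh17 day 2 replicate 3, 450, 401 and 359 without pTh17 day 2 replicates 1, 2 and 3. It was 385 and 359 without betaTh17 day 4 replicates 2 and 3, and 374 and 426 without pTh17 day 4 replicates 1 and 2, and rose to 1176 without betaTh17 day 4 replicate 1. Of the named genes, Blnk was lost without betaTh17 day 2 replicate 3 (0.0509) or pTh17 day 4 replicate 3 (0.0594), and Il2 without betaTh17 day 4 replicate 2 (0.0678). Pfkp was lost without any library but betaTh17 day 4 replicate 1 and pTh17 day 2 replicate 1 (0.0532 to 0.122), and Kdm3a without any but these 2 and betaTh17 day 2 replicate 2 (0.0558 to 0.115). Losses of Ndrg1 came without replicates 1 and 3 of betaTh17 day 2 and pTh17 day 4, pTh17 day 2 replicate 3 or betaTh17 day 4 replicate 2 (0.0506 to 0.0763). Those of Pdcd1 came without betaTh17 day 2 replicate 3, replicates 2 and 3 of pTh17 day 2 and betaTh17 day 4, or replicates 1 and 2 of pTh17 day 4 (0.0502 to 0.0924). Cd74 also passed without betaTh17 day 2 replicate 1 (0.0179), Gpi1 without pTh17 day 2 or betaTh17 day 4 replicate 1 (0.033, 0.0369) and Slc2a1 without pTh17 day 4 replicate 1 (0.0323).

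**Figure D4:**
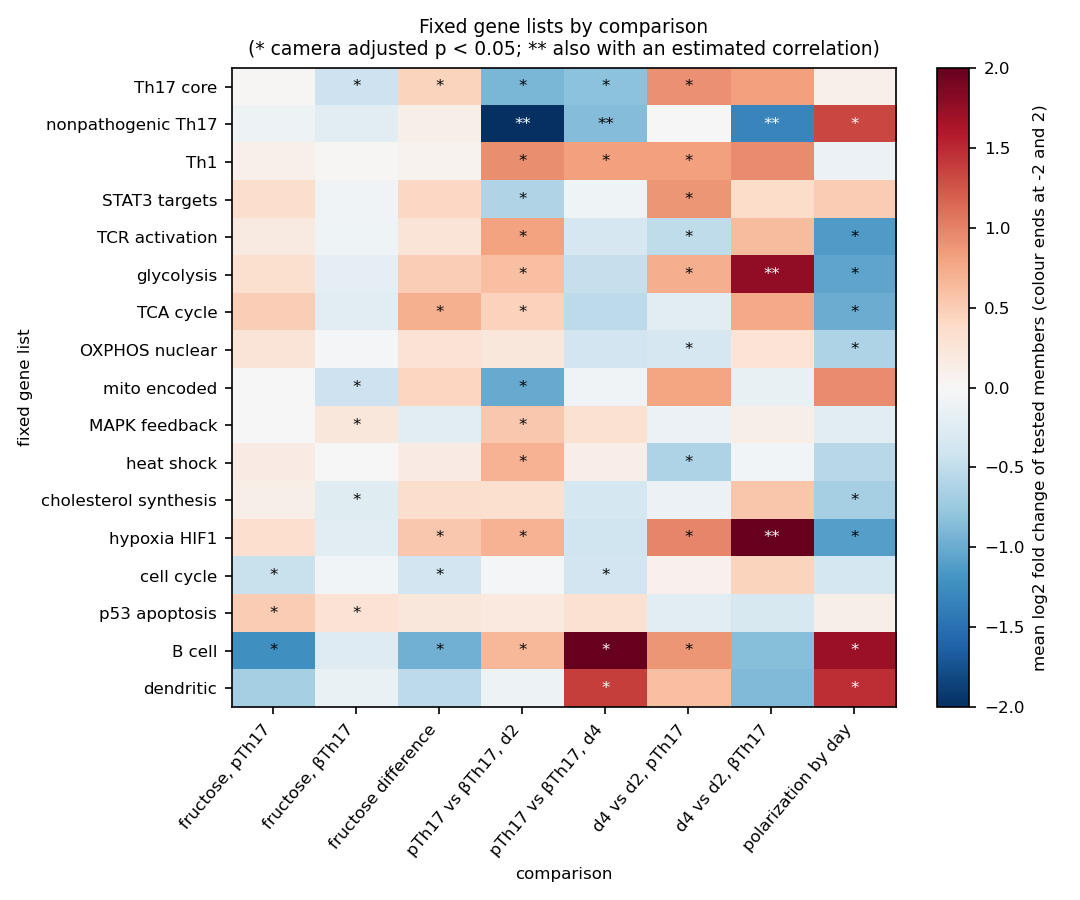
Mean log2 fold change of the tested members of each fixed gene list (vertical axis) in each of the 8 comparisons (horizontal axis), for lists that passed in at least 2 comparisons; colours end at -2 and 2. One star marks a camera adjusted p under 0.05 with the preset correlation, and a double star one that also passes with an estimated correlation, which holds for non-pathogenic Th17 genes in 3 comparisons and for glycolysis and hypoxia genes between the days in betaTh17 cells.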

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

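The tests of GC content and length below were added after the main results were seen. So were those of the Th17 program, of the averaged fructose effect and of the same-sign share.

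The B cell list was lower on average with fructose in pTh17 cells, with 3 of 10 members called and an adjusted p of 0.728 with an estimated correlation. Carry-over of B cells in the starting material, lost with fructose, is a candidate explanation that was not tested here. Measured values that bear on it are those of Cd79b, at 1.13 to 3.45 CPM, and Ms4a1, at 0.188 to 0.484 CPM, in untreated pTh17 day 4 libraries where Pax5 averaged 126 CPM. Over the 3 replicate pairs Pax5 changed by -2.40, -1.84 and -2.52 and Blnk by -2.25, -1.47 and -2.40. Cd79a changed by -1.48, -1.41 and -1.76 and Cd74 by -1.29, -0.90 and -1.27. Bank1, which is not on the list, changed by -1.46, -0.41 and -1.50. Ebf1 changed by -0.45, -0.37 and -0.07 and Ms4a1 by -0.03, -1.07 and -0.46. Cd79b and H2-Aa rose by 0.73 and 0.45 in pair 2 and fell in the others. H2-Ab1 also rose in pair 2, at 83.5, 156 and 109 CPM with fructose against 108, 130 and 180 CPM in controls 1 to 3. A trend with GC content and length does not account for the lower list mean, which was -1.29 with such offsets.

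Il17a was higher on average with fructose in pTh17 cells, without passing. Its log2 change lay at percentile 100 of the 200 genes nearest in GC content and length (with 1.69 as the upper end of the central 95%). This does not point to such a trend, but Il17a was examined because its change was large, so the rank carries little weight. Its highest value, 230 CPM, was that of fructose replicate 2, where GC-rich genes deviated by -0.21. More Th17 cells, or a stronger Th17 program, could raise Il17a. Of the 16 other core members 5 were above 0.5, with a list adjusted p of 0.654 by camera, so this stays open. The difference in the Il17a response between the polarizations was 2.16 with offsets and a within-day replicate block, against 2.25 with that block alone (adjusted p = 0.0265 and 0.0385), while the range over its alternatives was 1.61e-08 to 0.992. The betaTh17 control and fructose libraries did not meet the pairing check, so the block matches only part of this contrast.

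Counts of calls were compared with those of other splits of the same libraries. In the fructose comparisons, 10 splits are too few for a share under 0.05: 1 of 10 in pTh17 cells (80, highest other 0) and 2 of 10 in betaTh17 cells (1, highest other 2336, so betaTh17 libraries at day 4 differ in some other way than by fructose). The same limit holds for the polarizations at day 2 (1 of 10, 1438, highest other 0) and day 4 (1 of 10, 1061, highest other 0) and for the days in pTh17 (1 of 10, 2686, highest other 0) and betaTh17 cells (1 of 10, 4044, highest other 0). The fructose interaction has a real count of 0, so all 100 of 100 splits give as many (highest other 2696) and its splits test nothing. The averaged fructose effect gave 11 of 100 (161, highest other 2696), so chance is not excluded. Of the 10 other splits as large, 8 part the betaTh17 libraries as the split with 2336 calls does, and none of the 12 others that part all replicate pairs in both kinds of cell gave a call, too few for a share under 0.05. The polarization by day interaction gave 1 of 100 (721, highest other 720), where splits outside the random draw were not counted. The share of pTh17 fructose calls with the same sign in betaTh17 cells gave 1 of 10 (87.5% by mean log2 CPM, where the fitted changes give 85%; highest other 82.5%).

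In the polarization by day interaction 721 genes passed. Values for genes were Blnk 2.69, Cd79a 3.33, Ahr 1.82, Ffar1 5.94, Lhx6 7.65 and Olfm2 7.27 in the positive direction. In the negative direction they were Pfkp -1.74, Ak4 -2.30, Bnip3 -2.59, Kdm3a -1.3, Ndrg1 -1.75, Egr3 -2.17, Il2 -4.70, Nr4a3 -1.75, Pdcd1 -1.76, Cavin3 -5.40, Dgkk -8.12 and Ifitm3 -5.31. List means were 1.34 for non-pathogenic Th17, -1.13 for T cell receptor activation, -1.06 for glycolysis, -0.99 for the TCA cycle, -0.61 for nuclear OXPHOS, -0.67 for cholesterol synthesis, -1.10 for hypoxia, 1.73 for B cell and 1.48 for dendritic cell genes. Calls lost without a library were Blnk (0.0509 without betaTh17 day 2 replicate 3, 0.0594 without pTh17 day 4 replicate 3) and Il2 (0.0678 without betaTh17 day 4 replicate 2), and Pfkp, Kdm3a, Ndrg1 and Pdcd1 were lost without 6 to 10 of the libraries each.

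In the fructose interaction the list means were 0.44 for Th17 core, 0.71 for TCA cycle, 0.55 for hypoxia, -0.39 for cell cycle and -0.97 for B cell genes.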

How the results depend on the processing

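The within-day replicate block, the GC and length offsets, the 2 together and the removal of replicate 3 of the betaTh17 day 2 controls were added after results were seen. Counts of calls moved more than directions, but called and named genes were largely selected for a difference, which favours a steady direction. What moved the counts was not tested. Some adjusted p-values with no low-count filter were far smaller than the spread between libraries would lead one to expect, such as 3.63e-10 for Il22 between the polarizations at day 2. These may set the lower end of ranges given above. Fructose in pTh17 cells (80 calls) gave 1104 with no low-count filter, 384 with DESeq2, 0 with only the compared groups, 598 with the replicate block, 2085 with the within-day block, 133 with GC and length offsets, 2446 with offsets and the within-day block, 143 without replicate 3 of the betaTh17 day 2 controls, and 0 to 115 when a library was left out. Fructose in betaTh17 cells (1 call) gave 55 with no filter, 33 with DESeq2, 0 with only the compared groups, 12 with the replicate block, 51 with the within-day block, 3 with offsets, 60 with offsets and that block, 3 without replicate 3 of the betaTh17 day 2 controls, and 0 to 1 when a library of its own was left out. The fructose interaction (0 calls) gave 272 with no filter, 3 with DESeq2, 103 with the within-day block and 340 with offsets and that block. It stayed at 0 with RLE size factors, the replicate block, GC and length offsets alone and only the compared groups, and whenever a library was left out.

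The polarizations at day 2 (1438) gave 3091 with the within-day block, 3014 with offsets and that block, and 880 to 1527 when a library was left out. At day 4 (1061) they gave 2003 with no filter, 1629 with DESeq2, 2195 with the replicate block, 3469 with the within-day block, 3574 with offsets and that block, and 564 to 1482 when a library was left out. The days gave 4310 with only the compared groups and 1657 to 2432 when a library of its own was left out in pTh17 cells (2686; 3243 without replicate 3 of the betaTh17 day 2 controls), and 2462 to 4539 in betaTh17 cells (4044). The polarization by day interaction (721) gave 1763 with no filter, 1307 with DESeq2, 1812 with the replicate block, 3015 with the within-day block, 2360 with offsets and that block, and 359 to 1176 when a library was left out. Genes called with fructose in both kinds of cell (0) were 7 with the replicate block, 27 with the within-day block and 14 with DESeq2. Of 64 list calls, 5 remained with an estimated correlation and 80 were made with the replicate block. The mean of the pathogenic Th17 list under fructose in pTh17 cells was 0.19 to 0.92 when a library was left out, and that of the non-pathogenic list -0.29 to 0.31, with 0.09 without fructose replicate 1.

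Leaving out a library moved the log2 change of named genes by more than 1.5-fold for 10 of 35 with fructose in pTh17 cells, 21 of 31 in betaTh17 cells and 12 of 26 in the interaction. This held for 6 of 40 and 4 of 41 between the polarizations at day 2 and day 4, 0 of 30 and 1 of 22 between the days in pTh17 and betaTh17 cells, and 3 of 29 in the polarization by day interaction. Genes that the rule named outside the panel were chosen by their calls or by the direction of their list, which itself favours a steady direction. The named genes whose direction turned were, but for Xcr1, members of the panel. In fructose-treated pTh17 cells Il22 went to -0.11 with the replicate block, -0.14 with the within-day block, -0.00176 with offsets, -0.24 with offsets and that block and -0.25 to 0.77 without a library, and Il10 lay at -0.50 to 0.54. In betaTh17 cells they were Il10 (-0.27 to 0.38), Il17a (-1.24 to 0.21) and Il17f (-0.98 to 0.11), each without a library. In the interaction Csf2 went to -0.10 with offsets, -0.11 with offsets and the within-day block and -1.01 to 1.45 without a library, and Il10 lay at -0.57 to 0.45. Between the polarizations Il17a at day 2 went to -0.14 with offsets, -0.087 with offsets and the within-day block and -1.17 to 1.57 without a library, and at day 4 Xcr1 lay at -0.49 to 0.39 and Csf2 at -0.13 to 2.19 without a library.

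Fructose in betaTh17 cells (0.61, 0.65, 0.09) and the days in pTh17 (0.22, 0.01, 0.24) and betaTh17 cells (0.21, -0.06, 0.01) did not meet the pairing check of 0.1 for each replicate number. The replicate block there brought TCA cycle, unfolded protein response and hypoxia lists to an adjusted p of 0.0446 each with fructose. It gave 3557 calls between the days in pTh17 cells and 5336 in betaTh17 cells. Between the days the fructose and polyol list passed in pTh17 cells (0.0278), and in betaTh17 cells so did 7 lists (0.0142 to 0.0419): Th17 core, pathogenic Th17, Th1, fructose and polyol, unfolded protein response, cholesterol synthesis and CD8 T cell markers. In the fructose interaction the glycolysis list passed (0.0484). The replicate block changed no other list call than these and those beside the results.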

Other observations

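The fructose effects in pTh17 and betaTh17 cells were averaged, a contrast chosen after the results were seen. In the same edgeR fit 161 genes passed, 73 higher and 88 lower (1837 at an unadjusted p under 0.05; DESeq2 400, replicate block 411), and all 161 had the same sign in both kinds of cell, which selection on the average itself favours. Only the compared groups gave 78. Without a library it was 105, 97 and 60 for betaTh17 controls 1, 2 and 3, 104 and 103 for betaTh17 fructose 1 and 3, 71 and 60 for pTh17 controls 1 and 3, and 64 and 100 for pTh17 fructose 1 and 2. Adamts14, a procollagen-processing protease gene, stood at 20.6 ± 6.50 against 7.68 ± 1.63 CPM in pTh17 and 12.5 ± 3.59 against 4.03 ± 1.20 CPM in betaTh17 cells (log2 change 1.53, adjusted p = 0.0053). Other genes with the largest rises were Sp5 (2.34), Srpx2 (2.01), Slc13a3 (1.69), Foxq1 (1.64) and Dcxr (1.43), the last encoding the L-xylulose reductase of sugar metabolism. Those with the largest falls were Csf2rb (-2.84), Trabd2b (-2.42), Ciita (-2.03), Rnf217 (-1.85), Pld4 (-1.72) and Tlr12 (-1.65). Srpx2, Slc13a3, Adamts14, Csf2rb and Ciita passed with every library left out in turn (adjusted p up to 0.0471), while the other 7 were each lost without 5 to 10 of the libraries. B cell (-0.74, camera adjusted p = 1.59e-05), p53 (0.40, 0.000332), cell cycle (-0.25, 0.00227) and mTORC1 amino acid genes (-0.18, 0.0333) passed as lists, with adjusted p-values of 0.410 to 0.981 with an estimated correlation. As many calls came from 11 of 100 splits, so chance is not excluded. Of the 10 others, 8 were among the 12 that part the betaTh17 libraries as the split with 2336 calls does. The remaining 2 were among the other 87.

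Fructose in betaTh17 cells is a question for further work because a split of the libraries that mixes treated and untreated cultures gave 2336 calls where the real one gave 1. Libraries with replicate number 2, in both groups, lay with control replicate 3 in that split, which parts number 3 (r = 0.09 between its libraries), so replicate number alone does not account for it. These 3 libraries shared a composition: a median log2 deviation of GC-rich genes of -0.26, -0.34 and -0.26 (-0.08 to 0.11 in the other 3), ribosomal protein genes at 1.16%, 1.16% and 0.958% of counts (0.489% to 0.801%) and mitochondrial transcripts at 0.468%, 0.430% and 0.526% (0.303% to 0.308%). In pTh17 cells fructose replicate 2 shared it (-0.21, 1.24% and 0.733%). What produced this is not known. Pairs of cultures started from the same mouse, with the pairing recorded, would allow the replicate block, which gave 12 calls here, to be used as the planned test. An assay of EGFR protein and signalling would be needed as well, since transcript levels of Egfr differed by polarization but did not pass with fructose (log2 change 0.37 in pTh17 cells, adjusted p = 0.377).

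Whether Pax5 transcripts come from T cells could be tested by sorting or single-cell sequencing of untreated pTh17 cultures at day 4, since the B cell list had a mean of -1.23 with fructose (-1.29 with GC and length offsets; adjusted p = 0.728 with an estimated correlation). An osmotic control at 50 mM, such as mannitol, would separate fructose metabolism from osmolarity. The osmotic list had means of 0.42 in betaTh17 and 0.39 in pTh17 cells, and the design has no such control.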
